A study of Mus musculus with 6 samples.

How the data were processed

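Liver RNA of C57BL/6J mice aged 15 weeks was sequenced in 6 libraries, 3 labelled placebo and 3 labelled with a DHT pellet, per the labels. DHT is dihydrotestosterone, an androgen. The labels name the animals as a mouse model of polycystic ovary syndrome (PCOS) and give no sex, no collection time, no litter and no sequencing batch. Libraries were prepared with an NEB Ultra RNA kit and read in paired-end mode, per the labels.

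The values used here are gene counts that the authors deposited, 1 table per library. Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 and the genome build GRCm38 are named in the submitters' processing notes. Each deposited table holds whole-number counts for 49212 genes with their chromosome, start, end, strand and exon length, per the file headers. No value had been normalised, and 0 rows lacked a gene name. The strand setting, the treatment of reads that map to several places and whether reads or read pairs were counted are not given in the sources used here. Counts of genes whose exons overlap, and of near-identical family members, are therefore uncertain. Among named genes, exons overlap those of a counted neighbour over 62.4% of their length in Hsd3b7, 23.4% in Ccnd1, 23.2% in Ctgf, 21.3% in Sds, 16.5% in Srd5a1, 15.8% in Atp5o, 12.8% in Mogat1, 11.4% in Acaa1b, 4.7% in Cry2, 4.2% in Usp2, 4.0% in Ddit3, 3.0% in Abcg5 and at most 1.2% in others, besides the overlaps given with the results. Gene symbols were matched to a GENCODE annotation of GRCm38: 46885 of the 49212 symbols were found, 42547 of them with the same coordinates. Coordinates in the text are those in the deposited tables. The preset gene Tars1 was found under its symbol Tars.

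Total counts per library lay between 41336844 and 60209462, so that 3 counts in a single library corresponded to between 0.0498 and 0.0726 counts-per-million (CPM). The floor for a gene with no count was 3 counts over the pooled libraries of its group, which is a lower CPM. Intervals and floors cover counting error only, because they pool the counts of a group and leave out the spread between its libraries. The reads also carry no molecular identifiers. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom, over 15027 genes, was 104.65, between DHT libraries 1 and 2.

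The groups, the tests, the gene lists and the alternatives that are not named as added were fixed before the data were examined. The main comparison was DHT minus placebo in R 4.3.3 with edgeR 4.0.16: low counts were removed with filterByExpr by group, library sizes were scaled by TMM (factors 0.9214 to 1.082), and the quasi-likelihood test (glmQLFit with robust empirical Bayes, glmQLFTest) was run without covariates. All adjusted p-values of genes are from this test with Benjamini-Hochberg adjustment over 15126 genes, and a gene is called at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Mean CPM values given with an SD are TMM-scaled over the 3 libraries of a group, except those of the sex-linked genes, which are CPM of all gene counts. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of CPM is given with its exact 95% interval.

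Preset lists, 23 of pathways and 16 of cell types or sex-linked genes, were tested with camera on the edgeR fit with a preset inter-gene correlation of 0.01, adjusted over the lists of each family with at least 5 tested members. The lists were also tested with the correlation estimated per list, and with fry. Named genes follow a fixed rule: the 8 called genes with the largest change in each direction among those with a mean of at least 1 CPM and no overlap between the groups, the 3 members of each pathway list with the smallest p, the 2 such members of each marker list that was called or held a called gene, and 11 clock genes whatever their p. Some genes that the rule takes are not reported here and were not replaced, which leaves 88. Genes outside it are given as chosen after their values were seen.

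The alternatives were DESeq2 size factors in edgeR, library size without composition scaling, leaving out the 20 most counted genes and the mitochondrial genes, no low-count filter, at least 1 CPM in at least 3 libraries, the replicate number as a block, limma 3.58.1 voom with sample quality weights, DESeq2 1.42.0, a fit that was not robust, glmTreat against a fold of 1.5, and leaving out each library in turn. Added after seeing the data were the removal of gene length and GC trends per library, alone and with the replicate block, the removal of genes on X and Y, and the removal of both libraries numbered 3. The GC content was known for 97.3% of the genes tested.

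The placebo and DHT libraries share the numbers 1 to 3 in their titles, which say nothing of a shared litter, day or batch. Deviations from the group means correlated across genes at r = 0.246 for the libraries numbered 1, 0.145 for those numbered 2 and 0.602 for those numbered 3. All 3 values lay over 0.1, the bound set for treating the numbers as pairs, so the value with the replicate block stands beside each result whose call it changes or whose count it moves by more than 1.5 times. Placebo 1 correlated best with DHT 2 (r = 0.287) and placebo 2 with DHT 1 (r = 0.445), so the numbers 1 and 2 did not match each library with its closest partner. Deviations within a group sum to 0, so the correlation of the libraries numbered 3 tends to raise the values among those numbered 1 and 2, matched or crossed. Passing the bound is therefore no evidence that the numbers mark pairs, and results with the block depend on that assumption.

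The fits were tested on simulated data drawn from the means and library sizes of these 6 libraries over 15126 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For DHT against placebo, 4% of the 2-fold and 44% of the 4-fold changes were recovered, with 5 false calls. With the replicate block, 2% and 36% were recovered, with 6 false calls. In a simulation with the cholesterol synthesis list 2-fold lower, camera called 2 lists, that one and the male-biased list, which had not been changed. Simulated genes were drawn independently of each other, while the correlation estimated in the data was 0.645 for the cholesterol synthesis list. The simulation therefore cannot show how often camera calls unchanged lists in these data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.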

Results

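Liver RNA was compared between 3 placebo libraries and 3 libraries labelled with a DHT pellet, from C57BL/6J mice aged 15 weeks. DHT is dihydrotestosterone, an androgen given as a slow-release implant to model polycystic ovary syndrome (PCOS). The study's title asks how androgen acts on the circadian system of the liver in such mice. Total counts were 60209462, 55017590 and 52814320 in placebo libraries 1 to 3 and 59257416, 51734154 and 41336844 in DHT libraries 1 to 3. Mitochondrial genes took 4.96 ± 1.80% of the counts in placebo and 7.64 ± 1.07% in the libraries labelled DHT (SD, n = 3 each), and placebo 3 had the lowest share, 3.23%. The labels do not say that the libraries are from separate animals, so p-values measure only the spread between these samples.

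The libraries labelled DHT held transcripts of the Y chromosome at far higher levels than the placebo libraries, at 157 ± 12.1 against 1.70 ± 0.60 CPM over that chromosome. Ddx3y, an RNA helicase gene on Y (GRCm38 chromosome Y, 1260771 to 1286629), had 0.0703 ± 0.0254 CPM in placebo and 75.5 ± 3.21 CPM in the libraries labelled DHT (SD, n = 3 each). Eif2s3y, a translation initiation factor gene (chromosome Y, 1010543 to 1028847), had 0.0548 ± 0.0372 against 55.0 ± 6.58 CPM. Xist, the RNA that silences 1 X chromosome in cells with a pair of them (chromosome X, 103460375 to 103483217), went the other way, with 100 ± 117 CPM in placebo and 0.292 ± 0.233 in the libraries labelled DHT. The 3 placebo libraries held 2522, 1281 and 12404 counts of Xist, and the 3 labelled DHT held 12, 6 and 23.

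By edgeR's quasi-likelihood test, the log2 fold change (DHT minus placebo, ± SE) was 9.82 ± 0.36 for Ddx3y (adjusted p = 3.24e-05) and 9.74 ± 0.49 for Eif2s3y (adjusted p = 8.53e-05). Uty and Kdm5d, Y genes of histone demethylase families, are given as ratios because placebo held 2 and 1 counts. The ratio was 1120 for Uty (95% interval 309 to 9250, chromosome Y, 1096861 to 1245759) and 1710 for Kdm5d (307 to 67700, chromosome Y, 897788 to 956786). All 4 stayed called in each of the 6 fits that left out 1 library. The log2 fold change of Xist was −8.66 ± 1.19 (adjusted p = 0.013), and the call was lost without DHT 1 or DHT 2 (highest adjusted p = 0.0645). The labels give no sex for any library. Because these Y-linked transcripts were high in all 3 libraries labelled DHT and close to 0 in all 3 placebo libraries, the Y signal and the treatment label could not be separated in any comparison made here.

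**Figure D1:**
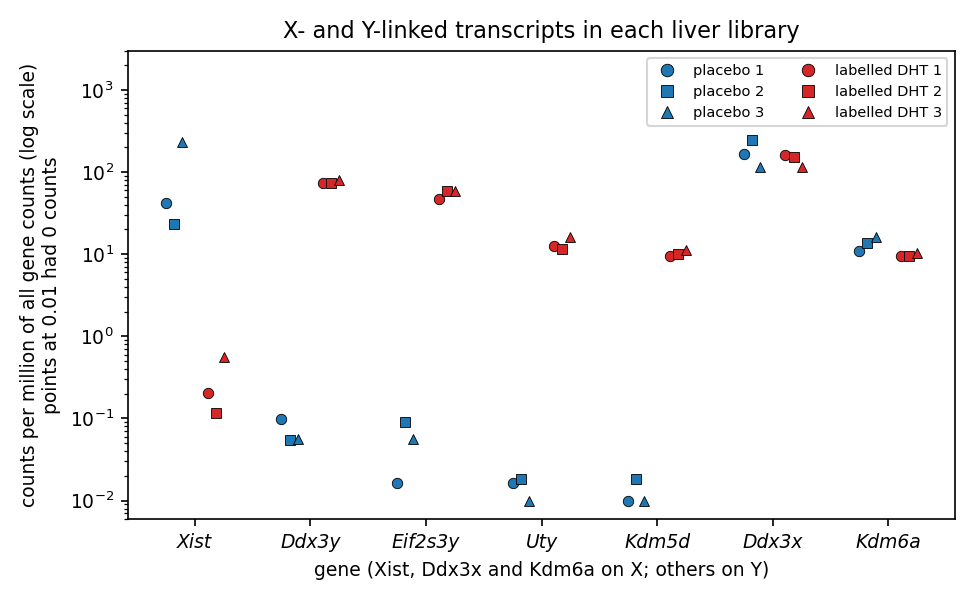
Transcripts of Xist, 4 Y-linked genes and their X-linked relatives Ddx3x and Kdm6a in each library, in CPM of all gene counts on a log axis, with placebo in blue and libraries labelled DHT in red, and points at 0.01 for 0 counts. The 4 Y-linked genes lie at or above 9.53 CPM in each library labelled DHT and at or below 0.0997 CPM in each placebo library.

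Of 6 tested genes that the annotation places on the Y chromosome, 5 were called, all higher. The other called one was Gm29650, with 0 counts in placebo and at least 37.1-fold higher in the libraries labelled DHT, a call lost without DHT 2 (adjusted p = 0.0611). The one not called was Erdr1 (log2 fold change 0.37 ± 0.52, adjusted p = 0.756). Of 453 X-linked genes, 3 were higher and 3 lower. Tmem28 (7.05 ± 0.46), Eda2r (2.68 ± 0.47) and Serpina7, which encodes the thyroxine-binding globulin (2.16 ± 0.36), were higher. Col4a5 (−2.56 ± 0.42) and Klhl13 (−1.52 ± 0.29) were lower with Xist. Xist and these 7 genes were chosen after their values were seen. Tmem28 stayed called in each of the 6 fits, while Eda2r, Serpina7, Col4a5 and Klhl13 were called, of those 6, only in the fit without placebo 3 (highest adjusted p = 0.241, for Klhl13 without DHT 2). Kdm6a, the X-linked relative of Uty, had a log2 fold change of −0.68 ± 0.25 (adjusted p = 0.242).

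Across the transcriptome, 250 of 15126 genes were called, 144 higher and 106 lower in the libraries labelled DHT, all by at least 2-fold. Leaving out X and Y, 135 were higher and 103 lower on the autosomes. At an unadjusted p under 0.05 there were 2409 genes. In 3573 genes (23.6%) the 2 groups did not overlap, where chance gives 10% for 3 against 3. A fit with the replicate number as a block called 1621 genes, 823 higher and 798 lower, among them 242 of the 250 in the same direction. Scaling by library size alone gave 207 higher and 89 lower, so that 69.9% of the calls were higher against 57.6% with TMM. The median log2 fold change of all genes moved from −0.0245 with TMM to 0.165 with library size alone. The count was 94, 105 and 862 without placebo 1, 2 and 3, and 95, 84 and 165 without DHT 1, 2 and 3.

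Genes that differ between male and female liver were among the largest changes. Cyp2c69, a cytochrome P450 gene known for its female-biased expression (chromosome 19, 39842660 to 39886769), fell by 9.76 ± 0.43 on the log2 scale, from 1029 ± 297.9 to 1.19 ± 0.0599 CPM (SD, n = 3 each). Sult2a2, a hydroxysteroid sulfotransferase gene (chromosome 7, 13733505 to 13779636), fell by 10.34 ± 0.45. In the other direction, Cyp4a12a, a male-biased fatty acid hydroxylase gene (chromosome 4, 115299046 to 115332815), rose 512-fold, from 0.243 ± 0.137 to 124 ± 59.1 CPM (adjusted p = 0.000806). Cyp2d9, a male-biased steroid hydroxylase gene (chromosome 15, 82452377 to 82456827), rose by 3.82 ± 0.38 on that scale.

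Of 28 female-biased genes tested, 17 fell and 1 rose, and adjusted over the list alone 27 fell and 1 rose (camera adjusted p = 1.27e-88). With an estimated correlation the list was still called (adjusted p = 0.0373, the highest over 19 alternatives, with 8.13e-124 the lowest). The member that rose was Cd36, a fatty acid transporter gene that the list of lipid droplet genes also holds. A1bg (−9.46 ± 0.42, chromosome 15, 60917589 to 60921270), Cyp2c40 (−8.07 ± 0.37, chromosome 19, 39767071 to 39812814), Sult2a1 (−9.89 ± 0.81, chromosome 7, 13796246 to 13837409) and Sult3a1 (−9.58 ± 1.05, chromosome 10, 33863935 to 33879475) were among those that fell. Adjusted p-values of Cyp2c69, Sult2a2, A1bg, Cyp2c40, Sult2a1 and Sult3a1 ran from 4.22e-05 to 0.00551, and these 6 stayed called in each fit that left out 1 library. Cyp3a41a, a female-biased member of the Cyp3a family (chromosome 5, 145694049 to 145720136), had a log2 fold change of −10.01 ± 1.59 (adjusted p = 0.0231) and was called, of the fits that left out 1 library, only in that without placebo 1 (up to 0.127 in the others). Sult2a5 (chromosome 7, 13623967 to 13670807), outside the list, had 1214 counts in placebo and 0 in the libraries labelled DHT and was at least 367-fold lower, a call lost without placebo 1 (adjusted p = 0.0508).

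Of 18 male-biased genes tested, 8 rose, 0 fell and 10 were not called, and adjusted over the list alone 10 rose and 0 fell (camera adjusted p = 3.52e-16). The mean log2 CPM over the list, relative to the placebo mean, was 1.88, 2.16 and 3.90 in DHT 1, 2 and 3. In placebo 1, 2 and 3 it was −0.507, −0.212 and 0.719. Of the 18 genes, 11, 10 and 16 lay above the range of placebo in DHT 1, 2 and 3, and 3, 2 and 0 below it. The list was not called with an estimated correlation (adjusted p = 0.179 with an estimated correlation, the highest over 19 alternatives, with 1.06e-27 the lowest). Cyp4a12b (8.86 ± 0.96, adjusted p = 0.00518, chromosome 4, 115411624 to 115439034) rose with its neighbour Cyp4a12a and lost its call without placebo 1 (adjusted p = 0.0508). Pitx3, a homeobox gene outside the list (chromosome 19, 46135685 to 46148326), had 0 counts in placebo and 372 in the libraries labelled DHT, at least 137-fold higher, and lost its call without placebo 1 (adjusted p = 0.0529). It lies next to Elovl3 (chromosome 19, 46131897 to 46135307), a male-biased elongase gene on the other strand, and reads of Elovl3 that run on are not separable from it without the strand setting. Counts of calls in the male-biased list were 4, 5 and 7 without placebo 1, 2 and 3 and 7, 5 and 7 without DHT 1, 2 and 3. In the female-biased list, genes that fell numbered 15, 11 and 16 and then 15, 11 and 14 in the same order. Cyp2c, Cyp3a41, Cyp4a12 and Sult2a copies are near-identical, so how reads were shared within each family is uncertain. The libraries in which these lists moved are the 3 with Y-linked transcripts (157 ± 12.1 CPM over the Y chromosome, against 1.70 ± 0.60 in placebo).

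**Figure D2:**
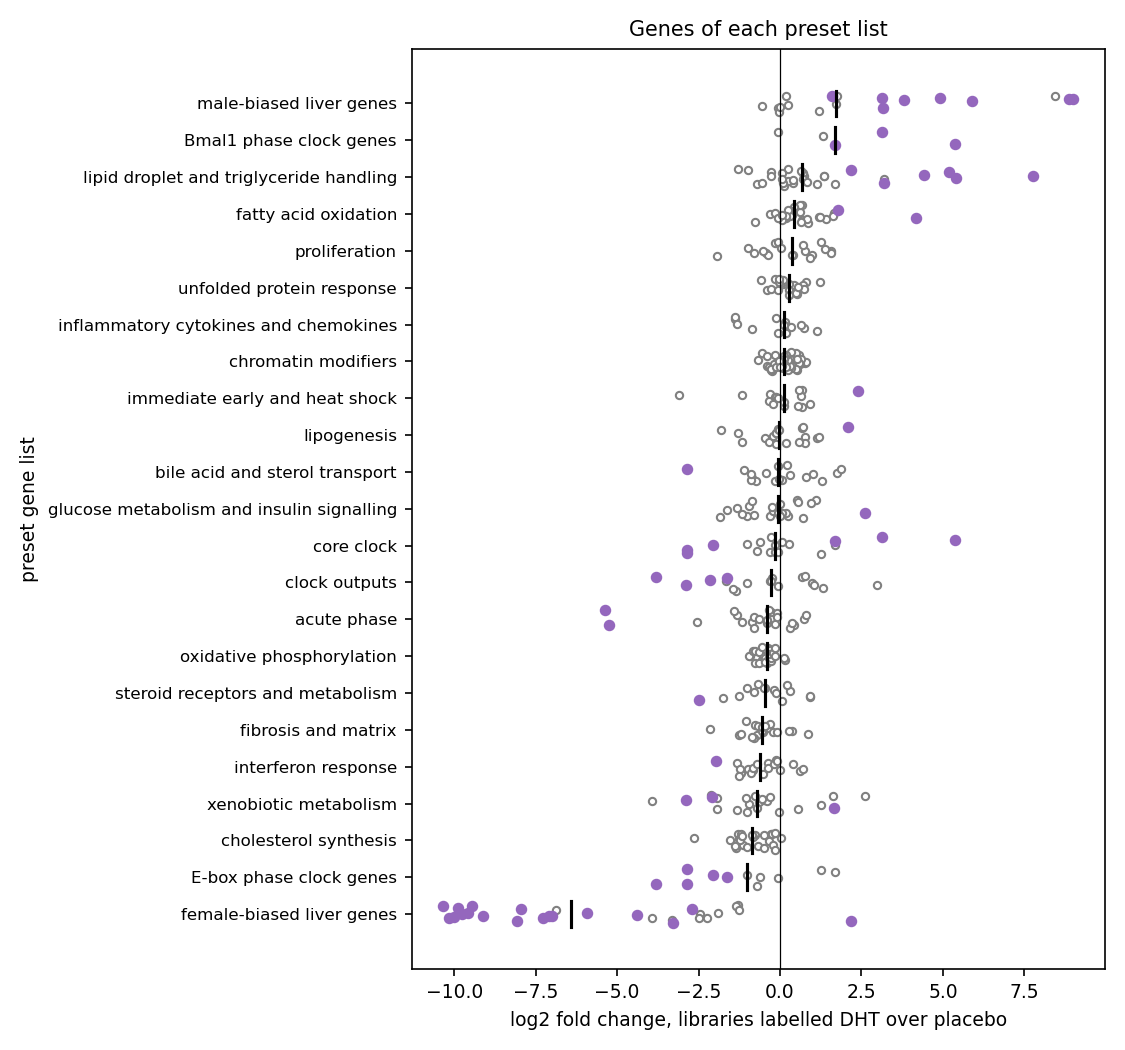
Log2 fold change, libraries labelled DHT over placebo, of each tested gene in the 23 preset pathway lists, with called genes filled, other genes open and the median of each list as a black bar. The medians run from −6.40 in the female-biased list to 1.73 in the male-biased list.

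Called clock genes split by the time of day at which they usually peak. Of 5 genes of the Bmal1 phase, 3 were called higher. Npas2, which encodes a partner of BMAL1 (chromosome 1, 39193731 to 39363236), rose 41.2-fold from 0.0578 ± 0.0221 to 2.46 ± 0.547 CPM (SD, n = 3 each). Arntl, which encodes BMAL1 (chromosome 7, 113207465 to 113314126), rose 8.71-fold, and Clock (chromosome 5, 76209868 to 76304792) rose 3.23-fold. Of 11 genes driven through E-boxes, the DNA element that BMAL1 and its partners bind, 5 were called lower. Usp2, a clock-controlled deubiquitinase gene (chromosome 9, 44067021 to 44095627), fell by 3.79 ± 0.39 on the log2 scale, and Ciart, a repressor gene (chromosome 3, 95878503 to 95882251), fell by 2.87 ± 0.36. Per1 (chromosome 11, 69095217 to 69109960) fell by 2.85 ± 0.43, Per3 (chromosome 4, 151003652 to 151044665) fell by 2.07 ± 0.37, and Dbp, an output transcription factor gene (chromosome 7, 45705088 to 45710203), fell by 1.63 ± 0.24.

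In log2 terms, the changes were 5.37 ± 0.47 for Npas2 (adjusted p = 0.00176), 3.12 ± 0.53 for Arntl (adjusted p = 0.0305) and 1.69 ± 0.32 for Clock (adjusted p = 0.0445). Adjusted p-values of the E-box genes were 0.00413 for Usp2, 0.0103 for Ciart, 0.0155 for Dbp, 0.0199 for Per1 and 0.038 for Per3. Nr1d1, which encodes the repressor REV-ERBα (chromosome 11, 98767932 to 98775333), had a log2 fold change of 1.70 ± 0.36 (adjusted p = 0.0693). It passed in 9 of 19 alternatives. Among them were the replicate block (adjusted p = 4.29e-06, the lowest over 19 alternatives, with 0.25 the highest) and the fit without placebo 3 (adjusted p = 0.0182). It also passed with gene length and GC trends removed (adjusted p = 0.0168). Nr1d1 belongs to the E-box list, so in those settings the called genes did not split by phase alone. Per2 (−0.71 ± 0.28, adjusted p = 0.273), Nr1d2 (−0.60 ± 0.37, adjusted p = 0.452), Cry2 (−0.30 ± 0.45, adjusted p = 0.775) and Cry1 (−0.05 ± 0.26, adjusted p = 0.944) did not pass. Without placebo 2 the log2 fold change was 0.13 for Cry1 and 0.36 for Cry2, and for Cry1 it was 0.08 without DHT 2 and 0.14 with library size alone, so these signs are not settled. Exons of Dbp overlap those of Sphk2 over 18.0% of their length on the opposite strand, and those of Nr1d1 overlap Thra over 8.5%, so their reads are uncertain without the strand setting.

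**Figure D3:**
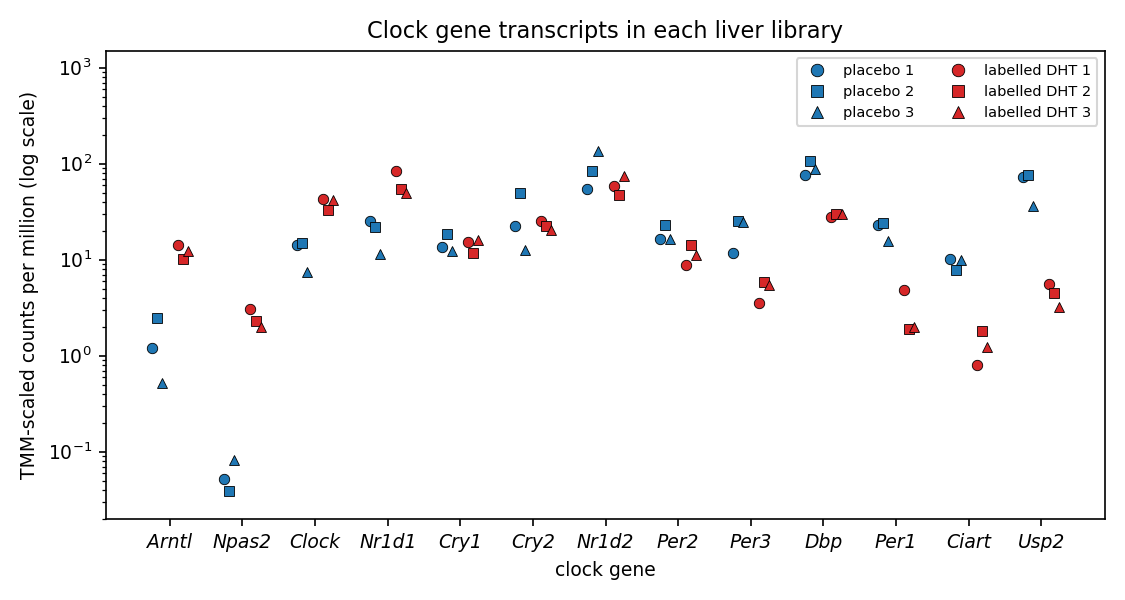
TMM-scaled CPM of 13 clock genes in each library on a log axis, with placebo in blue and libraries labelled DHT in red. Npas2 lies between 0.0394 and 0.0822 CPM in placebo and between 2.01 and 3.07 CPM in the libraries labelled DHT, and Usp2, Per1 and Ciart show no overlap in the opposite direction.

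Of 5 genes in the Bmal1 phase list, 3 rose and 0 fell, and adjusted over the list alone 4 rose and 0 fell (camera adjusted p = 2.79e-08, adjusted p = 0.177 with an estimated correlation, lowest over 19 alternatives 1.07e-10). Of 11 genes in the E-box phase list, 0 rose and 5 fell, and adjusted over the list alone 2 rose and 7 fell (camera adjusted p = 1.93e-07, adjusted p = 0.0936 with an estimated correlation, lowest over 19 alternatives 1.94e-09). The core clock list, which holds genes of both phases, had 3 of 18 genes higher and 3 lower, and adjusted over the list alone 4 higher and 4 lower (camera adjusted p = 0.858). Its median log2 fold change was −0.161, its mean was 0.133 and camera's direction was up, so median and mean differed in sign. Npas2 and Usp2 stayed called in each fit that left out 1 library. Ciart lost its call without placebo 1 (adjusted p = 0.0513), Dbp without any one DHT library (up to 0.12) and Per1 without placebo 1, placebo 2, DHT 2 or DHT 3 (up to 0.0936). Per3 lost it without placebo 2 or any one DHT library (up to 0.16), Arntl without placebo 1 or any one DHT library (up to 0.163), and Clock in each fit except that without placebo 3 (up to 0.177). Counts of E-box genes that fell were 3, 3, 6, 3, 2 and 2 without placebo 1, 2 and 3 and DHT 1, 2 and 3, and those of Bmal1 phase genes that rose were 1, 2, 3, 1, 1 and 1. In the core clock list, in the same order, 1, 2, 4, 1, 1 and 1 rose and 1, 1, 3, 2, 1 and 1 fell.

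Clock outputs were mostly lower where they changed: of 18 tested, 0 rose and 4 fell, Usp2, Dbp, Nampt and Por. Nampt, the rate-limiting enzyme gene of NAD salvage (chromosome 12, 32820335 to 32853369), fell by 2.15 ± 0.28 on the log2 scale (adjusted p = 0.0107). Por, which encodes the reductase that feeds electrons to cytochromes P450 (chromosome 5, 135670033 to 135735326), fell by 2.88 ± 0.39 (adjusted p = 0.0125). Adjusted over the list alone, 5 rose and 8 fell (camera adjusted p = 0.00139, adjusted p = 0.354 with an estimated correlation, lowest over 19 alternatives 6.67e-05). Under the replicate block 4 rose and 8 fell. Genes that fell numbered 3, 4, 7, 2, 1 and 3 without placebo 1, 2 and 3 and DHT 1, 2 and 3, and 1 rose without placebo 3. Nampt lost its call without DHT 1 or DHT 2 (up to 0.073) and Por without placebo 1 or DHT 2 (up to 0.0818). These clock and output genes split along the same 3 against 3 libraries as the Y-linked transcripts (Ddx3y 75.5 against 0.0703 CPM).

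Of 30 genes of lipid droplet and triglyceride handling, 6 were called higher and 0 lower. Plin4, a lipid droplet coat gene (chromosome 17, 56100591 to 56109803), rose 42.1-fold, from 0.382 ± 0.0889 to 16.3 ± 7.84 CPM (SD, n = 3 each). Cidec, which promotes fusion of lipid droplets (chromosome 6, 113424634 to 113435760), rose 36.3-fold, and Mogat1, a monoacylglycerol acyltransferase gene (chromosome 1, 78510991 to 78538173), rose 21.5-fold. Fgf21, a fasting-responsive hormone gene (chromosome 7, 45613886 to 45615490), rose 18.1-fold, from 0.606 ± 0.198 to 11.02 ± 5.24 CPM.

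Adjusted over the lipid droplet list alone, 11 of 30 genes rose and 0 fell (camera adjusted p = 1.19e-08, adjusted p = 0.264 with an estimated correlation, lowest over 19 alternatives 1.67e-18). The log2 fold changes were 5.40 ± 0.51 for Plin4 (adjusted p = 0.00271), 5.18 ± 0.63 for Cidec (adjusted p = 0.00865) and 4.43 ± 0.68 for Mogat1 (adjusted p = 0.0199). The other 3 that rose were chosen after their values were seen: Cidea, a relative of Cidec (7.77 ± 1.27), Cd36 (2.17 ± 0.39) and Fitm1, a gene of lipid droplet formation (3.18 ± 0.62). The call of Cidec was lost with the replicate block (adjusted p = 0.0823, range over 19 alternatives 8.26e-20 to 0.11). Plin4 stayed called in each fit that left out 1 library. Cidec lost its call without placebo 1 or 2 (up to 0.0666), and Mogat1, like Cd36, without placebo 1, placebo 2, DHT 1 or DHT 2 (up to 0.0816 and 0.134). Of these 6 fits, Cidea was called only in that without DHT 3 (up to 0.146 in the others) and Fitm1 only in that without placebo 3 (up to 0.143). Genes that rose numbered 1, 1, 8, 2, 2 and 6 without placebo 1, 2 and 3 and DHT 1, 2 and 3. DHT 3 stood below DHT 1 and 2 in Cidec (4796, 5157 and 1008 counts in DHT 1, 2 and 3) and Cidea (1526, 1597 and 59), while placebo held 66, 75 and 131 counts of Cidec and 9, 1 and 3 of Cidea. Of the adipocyte markers, Cfd rose as well (8.07 ± 1.11), while Adipoq had 1, 0 and 2 counts in placebo and 0, 0 and 1 in the libraries labelled DHT.

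Of 29 genes of fatty acid oxidation, 2 rose and 0 fell, and adjusted over the list alone 7 rose and 0 fell (camera adjusted p = 2.56e-06, adjusted p = 0.351 with an estimated correlation, lowest over 19 alternatives 3.71e-08). The replicate block gave 7 higher and 0 lower. Fgf21 had a log2 fold change of 4.18 ± 0.48 (adjusted p = 0.00709) and stayed called in each fit that left out 1 library. Acaa1b, a peroxisomal thiolase gene (chromosome 9, 119148023 to 119157093), rose by 1.78 ± 0.31 (adjusted p = 0.0332), a call kept, of the 6 fits, only without placebo 3 (up to 0.153 in the others). Pex11a, a peroxisome division gene (chromosome 7, 79735957 to 79743131), had 1.41 ± 0.30 (adjusted p = 0.0693), and passed without placebo 3 (adjusted p = 0.011) and with the replicate block (adjusted p = 0.000137, range over 19 alternatives 0.000137 to 0.25). Without placebo 3, 5 genes rose and 1 fell, and each other fit called 1. Lipogenesis showed no common movement, and the libraries labelled DHT differed. In DHT 1, 2 and 3 its mean log2 CPM relative to placebo was 0.0368, 0.821 and −0.587. In placebo 1, 2 and 3 it was −0.357, 0.432 and −0.0748. Genes above the range of placebo numbered 4, 11 and 2 in DHT 1, 2 and 3, and those below it 5, 2 and 10. As a list, 1 of 20 genes rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.553, median −0.0366, mean 0.122, direction up). That gene was Elovl5, a fatty acid elongase gene (chromosome 9, 77917364 to 77984519), with 2.09 ± 0.37 (adjusted p = 0.038), lost without placebo 1, placebo 2, DHT 1 or DHT 2 (up to 0.124). Thrsp (−1.80 ± 0.58, chromosome 7, 97412938 to 97417730) and Tkfc (1.13 ± 0.42, chromosome 19, 10592200 to 10604258) passed with the replicate block (adjusted p = 0.00756 and 0.00833, with highest values of 0.507 and 0.634 over 19 alternatives), which gave 3 higher and 2 lower. The list was called by camera without DHT 3 (adjusted p = 0.022, highest over 19 alternatives 0.926). The libraries compared here were also parted by Xist (0.292 CPM in the libraries labelled DHT against 100 in placebo).

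Cholesterol synthesis genes lay lower as a list, mainly in DHT 1 and DHT 3, with no single member called. The mean log2 CPM over the list, relative to the placebo mean, was −1.58, −0.137 and −1.18 in DHT 1, 2 and 3 and −0.147, 0.349 and −0.201 in placebo 1, 2 and 3, so that DHT 2 lay within the range of placebo. Of the 24 genes, 21, 7 and 20 lay below the range of placebo in DHT 1, 2 and 3. By edgeR 0 of 24 were called over all genes and 0 adjusted over the list alone, while 8 were lower at an unadjusted p under 0.05, 4 by DESeq2, 1 by limma voom and 12 with the replicate block (camera adjusted p = 1.56e-06, adjusted p = 0.442 with an estimated correlation, lowest over 19 alternatives 2.22e-18, without DHT 2). Pmvk, the phosphomevalonate kinase gene (chromosome 3, 89454541 to 89469013), had a log2 fold change of −1.28 ± 0.38 (adjusted p = 0.167). Fitted with the replicate block, it passed at adjusted p = 0.000312, with a highest value of 0.47 over 19 alternatives. Of the list, 1 gene was called lower without placebo 3 and 1 without DHT 2, against 0 in the other 4 fits that left out 1 library. The libraries compared were also parted by Y-linked transcripts (Kdm5d 10.3 against 0.00606 CPM).

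Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis (chromosome 4, 6265612 to 6275633), fell by 2.84 ± 0.31 on the log2 scale, from 274.8 ± 53.4 to 38.3 ± 9.51 CPM (SD, n = 3 each, adjusted p = 0.00518), and stayed called in each fit that left out 1 library. It was the only one of 18 genes of bile acid and sterol transport called, over all genes or adjusted over the list alone (0 rose, 1 fell, camera adjusted p = 0.57). Under the replicate block 4 rose and 2 fell, among them Hsd3b7 (1.30 ± 0.38 without the block, adjusted p = 0.164) and the sterol transporter gene Abcg5 (−1.09 ± 0.32, adjusted p = 0.156), at adjusted p = 0.00833 and 0.00996 (highest over 19 alternatives 0.436 and 0.485). Both also passed without placebo 3 (adjusted p = 0.045 and 0.0366), where 1 gene rose and 2 fell, and without placebo 2 the list had 1 higher and 1 lower. Exons of Hsd3b7 overlap those of 9430064I24Rik over 62.4% of their length.

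Of 23 genes of glucose metabolism and insulin signalling, 1 rose and 0 fell, and adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.57). The gene was Ppp1r3c, which targets a phosphatase to glycogen (chromosome 19, 36731737 to 36736653), at 2.60 ± 0.48 (adjusted p = 0.0407), a call kept, of the 6 fits that left out 1 library, only without placebo 3 (up to 0.124 in the others). Igf1 (−1.02 ± 0.25, adjusted p = 0.102, chromosome 10, 87858265 to 87937042) and Igfbp2 (−1.83 ± 0.49, adjusted p = 0.128, chromosome 1, 72824503 to 72852474) did not pass. With the replicate block 3 rose and 4 fell, with Igf1 at adjusted p = 0.0306 and Igfbp2 at 2.56e-05 (highest over 19 alternatives 0.39 and 0.375). Without placebo 3, 1 rose and 3 fell, with Igf1 at adjusted p = 0.03, and 0 were called in each other fit.

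In the list of steroid receptors and metabolism, 0 of 15 genes rose and 1 fell, and adjusted over the list alone 2 rose and 4 fell (camera adjusted p = 0.0488, adjusted p = 0.351 with an estimated correlation, lowest over 19 alternatives 0.0161). The gene was Esr1, the oestrogen receptor alpha gene (chromosome 10, 4611593 to 5005614), at −2.48 ± 0.35 (adjusted p = 0.0141), lost without placebo 1, placebo 2, DHT 2 or DHT 3 (up to 0.0891). The list was not called without placebo 2 (adjusted p = 0.156) or DHT 3 (0.185), nor with library size alone (0.0568), at least 1 CPM in 3 libraries (0.0745), voom (0.17), both libraries numbered 3 left out (0.123) or fry's directional test (0.0686). With the block 2 rose and 3 fell. Hsd17b6 (−1.75 ± 0.37, adjusted p = 0.0669 without the block, chromosome 10, 127990941 to 128000678) passed at adjusted p = 2e-05 and Srd5a1, a steroid 5-alpha reductase gene (0.93 ± 0.21, adjusted p = 0.0852 without it, chromosome 13, 69573449 to 69611442), at 0.0138 (highest over 19 alternatives 0.267 and 0.36). Without placebo 3, 1 rose and 3 fell, with Hsd17b6 and Srd5a1 at adjusted p = 0.024 and 0.0312, without DHT 1 Esr1 alone was called, and 0 were called in the other 4 fits.

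Of 23 genes of xenobiotic metabolism, 1 rose and 2 fell, and adjusted over the list alone 2 rose and 8 fell (camera adjusted p = 9.3e-05, adjusted p = 0.351 with an estimated correlation, lowest over 19 alternatives 3.84e-06). Por and Ces2a, a carboxylesterase gene (−2.08 ± 0.29, adjusted p = 0.0137, chromosome 8, 104734003 to 104741634), fell. Gclc, which makes the first product of glutathione synthesis (1.64 ± 0.27, adjusted p = 0.0259, chromosome 9, 77754535 to 77794485), rose. Blocking by replicate number gave 2 higher and 9 lower. Genes that fell numbered 0, 1, 5, 2, 0 and 2 without placebo 1, 2 and 3 and DHT 1, 2 and 3, and genes that rose 0, 0, 1, 0, 0 and 1. Gclc was called in the fit without placebo 3 but in none of the other 5 (up to 0.123). Ces2a lost its call without placebo 1, placebo 2, DHT 1 or DHT 2 (up to 0.0818). The libraries with lower Esr1, Por and Cyp7a1 were those with Y-linked transcripts (Eif2s3y 55.0 against 0.0548 CPM).

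Metallothioneins fell: Mt1 (chromosome 8, 94179082 to 94180327), which binds zinc, fell by 5.26 ± 0.64 on the log2 scale, from 289.6 ± 117 to 7.56 ± 5.30 CPM (SD, n = 3 each, adjusted p = 0.00862), and Mt2 (chromosome 8, 94172664 to 94173568) fell by 5.37 ± 0.69 (adjusted p = 0.0105). They were the 2 of 22 genes in the acute phase list that fell, with 0 higher, over all genes and adjusted over the list alone (camera adjusted p = 0.000595, adjusted p = 0.264 with an estimated correlation, lowest over 19 alternatives 2.45e-05). Both are induced by metals and glucocorticoids as well as in the acute phase. Mt1 stayed called in each fit that left out 1 library, and Mt2 lost its call without placebo 1 (adjusted p = 0.0545), while 3 genes fell without placebo 3. Apcs (−1.30 ± 0.44, adjusted p = 0.209) passed with the replicate block (adjusted p = 0.00948, highest over 19 alternatives 0.537). Mt1 and Mt2 are similar in sequence, and RP23-98C9.5 overlaps 73.5% of the exons of Mt2, with 750 counts against 10442. The libraries with low Mt1 were those with Y-linked transcripts (Uty 13.6 against 0.0116 CPM).

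In the interferon response list, 0 of 20 genes rose and 1 fell, and adjusted over the list alone 1 rose and 9 fell (camera adjusted p = 0.000401, adjusted p = 0.351 with an estimated correlation, lowest over 19 alternatives 1.03e-05). Zbp1, a sensor of unusual nucleic acids (chromosome 2, 173206612 to 173218923), was the one, at −1.97 ± 0.30 (adjusted p = 0.0199), and was called without placebo 3 or DHT 2 but not in the other 4 fits (up to 0.117). With the block 0 rose and 8 fell, with Irf7 (−1.20 ± 0.25, adjusted p = 0.0659 without the block) at 0.000945 and Ifit3 (−0.98 ± 0.27, adjusted p = 0.135 without it) at 0.0126 (highest over 19 alternatives 0.326 and 0.482). Without placebo 3, 4 fell, with Irf7 at adjusted p = 0.0215 and Ifit3 at 0.0431, and 0 or 1 in the other fits.

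Of 13 inflammatory cytokines and chemokines, 0 were called by edgeR, 4 were lower at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma voom and 3 with the replicate block. Adjusted over the list alone 0 rose and 2 fell (camera adjusted p = 0.398, median 0.136, mean −0.138, direction down). Vcam1 (−1.37 ± 0.33, adjusted p = 0.0943) and Nfkbia (−0.87 ± 0.23, adjusted p = 0.128) passed with the block (adjusted p = 0.000454 and 0.0226, highest over 19 alternatives 0.293 and 0.467) and without placebo 3 (0.0231 and 0.0408), a fit that called 1 higher and 2 lower, and Ccl5 (−1.39 ± 0.51, adjusted p = 0.246) did not. In this list and the interferon list the libraries compared were also parted by Y-linked transcripts (Ddx3y 75.5 against 0.0703 CPM).

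Of 17 immediate early and heat shock genes, 1 rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.272). Hspb1, a small heat shock protein gene (chromosome 5, 135887919 to 135889563), was the one, at 2.38 ± 0.30 (adjusted p = 0.00963), lost without placebo 1 or 2 (up to 0.0555). Ier2 (−1.16 ± 0.33, adjusted p = 0.152) passed with the replicate block, which called 1 higher and 1 lower (adjusted p = 0.00624, highest over 19 alternatives 0.473), and without placebo 3 (adjusted p = 0.0474). Egr1 had −3.08 ± 1.26 (adjusted p = 0.29), with 54.1 ± 84.8 CPM in placebo, and changed sign without placebo 1 (0.28). The list was called by camera without placebo 1 (adjusted p = 0.0122, highest over 19 alternatives 0.78).

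Chromatin modifiers, listed because the study's title asks about epigenetic regulation, had no called gene. By edgeR 0 of 45 were called over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom and 1 with the replicate block (camera adjusted p = 0.261, and 0.046 without placebo 2, range over 19 alternatives 0.046 to 0.981). The smallest p-values were those of Hdac8 (0.77 ± 0.27, adjusted p = 0.222), Kdm6a (−0.68 ± 0.25, adjusted p = 0.242) and Hdac1 (−0.57 ± 0.22, adjusted p = 0.254). In simulated data only 4% of 2-fold changes were recovered at this depth and spread, so changes of that size were mostly not detectable.

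In the unfolded protein response list, 0 of 22 genes were called by edgeR, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05, 1 by DESeq2, 1 by limma voom and 3 with the block (camera adjusted p = 0.166, and 0.0247 without DHT 2, highest over 19 alternatives 0.729). Ddit3 (1.22 ± 0.36, adjusted p = 0.164) and Creld2 (0.80 ± 0.40, adjusted p = 0.363) passed with the block (adjusted p = 0.0035 and 0.0422, highest over 19 alternatives 0.427 and 0.736), and Ddit3 also without placebo 3 (adjusted p = 0.0111), while Chac1 had −0.57 ± 0.32 (adjusted p = 0.407).

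In the fibrosis and matrix list, 0 of 20 genes were called by edgeR, with 3 lower at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma voom and 5 with the replicate block, and adjusted over the list alone 0 rose and 1 fell (camera adjusted p = 0.0225, adjusted p = 0.729 with an estimated correlation, lowest over 19 alternatives 0.000142). The camera call was lost without placebo 1 (adjusted p = 0.568) and without DHT 3 (adjusted p = 0.363), and the list mean, relative to placebo, was −0.194, 0.0765 and −1.24 in DHT 1, 2 and 3 against 0.842, −0.0808 and −0.761 in placebo 1, 2 and 3. The stellate cell marker list lay lower as well (camera adjusted p = 0.0385, adjusted p = 0.681 with an estimated correlation). Its mean was −0.29, −0.536 and −0.718 in DHT 1, 2 and 3. In placebo 1, 2 and 3 it was 0.623, −0.389 and −0.234, so that DHT 1 lay within the range of placebo. Ctgf (−2.14 ± 0.48, adjusted p = 0.082), Lum (−1.25 ± 0.34, adjusted p = 0.138) and Sparc (−1.05 ± 0.35, adjusted p = 0.209) passed with the block (adjusted p = 1.51e-05, 0.00529 and 0.0169, highest over 19 alternatives 0.284, 0.406 and 0.485), and Ctgf without placebo 3 (adjusted p = 0.0339), where 2 genes fell.

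Of 27 oxidative phosphorylation genes, 0 were called by edgeR over all genes or adjusted over the list alone, with 2 lower at an unadjusted p under 0.05 and 0 by DESeq2, limma voom or the block. The list lay lower (camera adjusted p = 0.00715, adjusted p = 0.729 with an estimated correlation, lowest over 19 alternatives 0.000514), but was not called without placebo 3 (adjusted p = 0.393) or without both libraries numbered 3 (0.106). Its mean relative to placebo was −0.408, −0.484 and −0.206 in DHT 1, 2 and 3 against −0.269, −0.228 and 0.497 in placebo 1, 2 and 3, so the groups overlapped. The mitochondrial share of counts was higher in the libraries labelled DHT, at 7.64 ± 1.07% against 4.96 ± 1.80%, with overlapping ranges (6.83% in placebo 1 and 6.438% in DHT 1). Placebo 3 also had the highest share of ribosomal protein genes, 4.345% against 1.083% to 2.031% in the others, and the lowest sample quality weight, 0.1917. Atp5o had −0.92 ± 0.39 (adjusted p = 0.303), Ndufs7 −0.56 ± 0.24 (adjusted p = 0.31) and Ndufv2 −0.76 ± 0.41 (adjusted p = 0.395). Of 19 proliferation genes, 0 were called by edgeR over all genes or adjusted over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma voom and 3 with the block (camera adjusted p = 0.272, and 0.00842 without placebo 1, highest over 19 alternatives 0.78). Ccnd1 (−1.93 ± 0.47, adjusted p = 0.0976), Ccnb2 (1.57 ± 0.44, adjusted p = 0.141) and Mki67 (1.56 ± 0.54, adjusted p = 0.225) passed with the block (adjusted p = 2.63e-07, 0.0157 and 0.00162, highest over 19 alternatives 0.318, 0.481 and 0.572), and Ccnd1 without placebo 3 (adjusted p = 0.0133).

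Camera called 14 of the 23 pathway lists, 4 higher and 10 lower, and with an estimated correlation only the call of the female-biased list held. Called higher were the lists of male-biased genes, Bmal1 phase genes, lipid droplet genes and fatty acid oxidation. Called lower were those of female-biased genes, E-box phase genes, clock outputs, cholesterol synthesis, xenobiotic metabolism, interferon response, acute phase, oxidative phosphorylation, fibrosis and steroid metabolism. Of these 14, the lists of cholesterol synthesis, steroid metabolism, xenobiotic metabolism, interferon response, fibrosis and oxidative phosphorylation had a camera p at least as small in some other split of the 6 libraries into 3 against 3.

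Of 16 marker lists, 12 had no called gene: over their 93 tested genes edgeR called 0, with 21 at an unadjusted p under 0.05, 6 by DESeq2, 3 by limma voom and 14 with the replicate block. Without placebo 3, the pericentral, stellate, cholangiocyte and erythroid lists had 1 called gene each. Camera called the periportal hepatocyte list lower (0 of 11 called, adjusted over the list alone 0 rose and 2 fell, camera adjusted p = 0.00188, adjusted p = 0.533 with an estimated correlation), with Sds, a serine dehydratase gene, at −1.51 ± 0.44 (adjusted p = 0.153) and Ctsc at −0.97 ± 0.27 (adjusted p = 0.145). Fitted with the block, 5 of these fell, Sds at adjusted p = 9.91e-05 and Ctsc at 0.0109 (highest over 19 alternatives 0.459 and 0.493). The stellate cell list was called lower too (0 of 9 called, 0 adjusted over the list alone, camera adjusted p = 0.0385, adjusted p = 0.681 with an estimated correlation), with Colec11 at −0.87 ± 0.31 and Ecm1 at −1.08 ± 0.40, which passed with the block (adjusted p = 0.0471 and 0.0231, highest over 19 alternatives 0.594 and 0.567) and, for Ecm1, without placebo 3 (adjusted p = 0.0286). The mean of the stellate cell list in DHT 1 (−0.29) lay within the range of placebo. In the T and NK cell list 1 of 8 fell, and 2 adjusted over the list alone or with the block (camera adjusted p = 0.00333, adjusted p = 0.533 with an estimated correlation). It was Gzma, a granzyme gene, at −2.62 ± 0.49 (adjusted p = 0.0414), called, of the 6 fits, only without placebo 3 (up to 0.176 in the others), beside Nkg7 at −1.46 ± 0.44 (adjusted p = 0.166).

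The sex-linked list was called (4 higher and 1 lower of 5, over all genes and adjusted over the list alone, camera adjusted p = 3.23e-48, adjusted p = 0.00518 with an estimated correlation). The other lists were not: hepatocyte (camera adjusted p = 0.0902), sinusoidal endothelial cell (0.0756), cholangiocyte (0.226), pericentral hepatocyte (0.582), erythroid (0.868), Kupffer cell, monocyte-derived macrophage and B cell (each 0.981). In the macrophage list the median was 0.0487, the mean −0.00242 and camera's direction down. Adjusted over the list alone, 3 cholangiocyte genes, 1 hepatocyte and 1 pericentral gene fell, 1 erythroid gene rose, and the other 4 lists had 0. The neutrophil, adipocyte, pancreatic acinar and muscle lists had 4, 3, 1 and 2 tested genes, too few for camera, and the neutrophil and muscle lists had 0 called, over all genes or adjusted over the list alone. In the adipocyte list Cfd, the complement factor D gene (chromosome 10, 79890853 to 79892656), rose by 8.07 ± 1.11 (adjusted p = 0.0134), from 3, 4 and 7 counts in placebo to 270, 803 and 2475 in the libraries labelled DHT, and lost its call without any one placebo library (up to 0.109) and by voom (adjusted p = 0.206, lowest over 19 alternatives 2.99e-21). The adipocyte genes Adipoq and Plin1 lay below the count filter, with 1, 0 and 2 counts of Adipoq in placebo and 0, 0 and 1 in the libraries labelled DHT. Car3, of the same list but also expressed in these livers (1492 ± 527.5 CPM in placebo), had 1.35 ± 0.32 (adjusted p = 0.0967) and passed with the block (adjusted p = 0.00574, range over 19 alternatives 0.00452 to 0.293), and adjusted over the list alone 2 of 3 rose, 3 with the block. The 1 acinar gene tested, Cela2a (chromosome 4, 141814962 to 141826160), fell by 4.99 ± 0.76 (adjusted p = 0.0199), from 1.29 ± 0.770 to 0.0412 ± 0.0418 CPM, and lost its call without placebo 1, placebo 2, DHT 1 or DHT 2 (up to 0.105). Its exons overlap those of Casp9 over 5.5% of their length, with 5235 counts of Casp9 against 204. The libraries with high Cfd and low Gzma were those with Y-linked transcripts (157 ± 12.1 against 1.70 ± 0.60 CPM over the Y chromosome).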

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

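The removal of gene length and GC trends, the removal of genes on X and Y and the removal of both libraries numbered 3 were alternatives chosen only after the data had been seen, and the others were planned. Of the genes called in the comparison, 0 changed sign in the 20 alternatives where they were tested, which leaves out 37 of them with at least 1 CPM in 3 libraries, 11 without X and Y and 1 without the 20 most counted and the mitochondrial genes. Against 250 genes called, 521 were called with no low-count filter, 744 by voom with sample quality weights, 1008 by DESeq2, 531 with the length and GC trends removed and 448 without both libraries numbered 3. Of the 250, the same direction and call were kept by 243 with no low-count filter, 238 by voom, 250 by DESeq2, 246 with the trends removed and 222 without both libraries numbered 3. The replicate block gave 1621, and 1605 with the trends removed as well, each with 242 of the 250. Leaving out 1 library at a time gave 84 to 862 genes, the highest without placebo 3. Why these counts differ was not tested. Of 23 pathway lists, camera called 14, with an estimated correlation 1, fry's directional test 3 (E-box phase, Bmal1 phase and female-biased genes) and fry's mixed test 16, some of which camera did not call.

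Direction changed for some lists and genes that were not called, and the cause was not tested. Scaling by library size alone gave a mean log2 fold change of 0.156 in the bile acid list, 0.0392 in the glucose list and 0.0449 in the inflammatory list, and 0.14 for Cry1, with the median of all genes at 0.165. With no low-count filter the inflammatory list had 0.0515. For the bile acid list, the mean was 0.0375 with the replicate block, 0.0551 by voom and 0.0509 with the block and the length and GC trends removed. Over the 6 fits that left out 1 library, list means ran from −0.348 to 0.381 for lipogenesis, −0.212 to 0.198 for bile acids, −0.284 to 0.0471 for glucose, −0.00321 to 0.228 for chromatin modifiers, −0.338 to 0.131 for inflammatory genes and −0.0776 to 0.558 for immediate early genes. Log2 fold changes in those fits ran from −0.66 to 0.36 for Cry2, −0.17 to 0.13 for Cry1 and −3.64 to 0.28 for Egr1.

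Some calls were lost under settings not named above. Cyp4a12b was not called by voom (adjusted p = 0.152), nor was Cyp3a41a by voom (0.128), with no low-count filter (0.177) or without both libraries numbered 3 (0.0803), nor Xist with no low-count filter (0.0883). Cidea was lost by voom (0.284) and with no low-count filter (0.148), Ppp1r3c with at least 1 CPM in 3 libraries (0.0552), Per3 without both libraries numbered 3 (0.0631), Gzma with library size alone (0.0507) and without both libraries numbered 3 (0.0743), and Klhl13 with library size alone (0.0596) and without both libraries numbered 3 (0.0639). Fitm1, at 0.0494, passed the threshold in 10 of 19 alternatives. Of 116 genes named, the replicate block ended the calls of Cidec and Elovl3, added 30 and left 84 on their side of the threshold. No camera call of the 23 pathway lists was changed by it. Simulated changes of 2-fold were recovered in 4% of genes and those of 4-fold in 44%, so a gene without a call may have changed by those sizes.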

Other observations

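The genes in this paragraph and the next were chosen after their values were seen, and of the tests below only the splits of the libraries and the length and GC test of the libraries numbered 3 were set before their results were seen. Cux2, a female-biased transcription factor gene of liver (chromosome 5, 121856366 to 122050102), fell from 25.5 ± 12.7 to 0.198 ± 0.0476 CPM (SD, n = 3 each, log2 fold change −7.00 ± 0.54, adjusted p = 0.00111). Lepr, the leptin receptor gene (chromosome 4, 101717404 to 101815352), fell by 3.12 ± 0.33 (adjusted p = 0.0047), and Upp2, a liver uridine phosphorylase gene (chromosome 2, 58567298 to 58792971), fell by 4.52 ± 0.51 (adjusted p = 0.00615). Insig2, which holds back the processing of SREBP (chromosome 1, 121304353 to 121332589), rose by 2.81 ± 0.33 (adjusted p = 0.00861). Cux2, Lepr, Upp2 and Insig2 stayed called in each of the 6 fits that left out 1 library. Lifr, the receptor gene of leukaemia inhibitory factor (−2.17 ± 0.38), and Apom, an apolipoprotein gene (−1.82 ± 0.30), fell, and Inhbe, the activin E gene (2.88 ± 0.43), and Gpd1, which makes glycerol 3-phosphate (1.90 ± 0.29), rose. These 4 lost their calls without placebo 1, placebo 2, DHT 1 or DHT 2 (highest adjusted p = 0.161 for Lifr, 0.14 for Apom, 0.0733 for Inhbe and 0.096 for Gpd1). Scp2, a sterol carrier gene (1.44 ± 0.27), and Crat, the carnitine acetyltransferase gene (1.95 ± 0.37), rose, and of the 6 fits were called only in that without placebo 3 (up to 0.2 and 0.173 in the others).

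Among male-biased genes, Elovl3 rose by 5.91 ± 0.86, from 4.98 ± 3.92 to 298 ± 142 CPM, and lost its call without placebo 2 or 3 (up to 0.0763) and with the replicate block (adjusted p = 0.11, range over 19 alternatives 2.28e-17 to 0.118). Mup20, a major urinary protein gene (4.92 ± 0.75, adjusted p = 0.0199), rose and lost its call without placebo 1 or DHT 2 (up to 0.139). Mup21 (5.45 ± 0.85, adjusted p = 0.0212) rose and was called without DHT 1 or DHT 3 but not in the other 4 fits (up to 0.136), and Mup copies share reads. A cluster of zinc finger genes on chromosome 4 held 4 called genes, all higher, which span 146239954 to 147642513. Of 10 genes tested in that span, 4 were called and all 10 had a log2 fold change above 0. The share called over all genes would give 0.165, but the span was set by the called genes, so this is not a test. Zfp979 rose by 3.84 ± 0.46 (adjusted p = 0.0081, lost without placebo 1 at 0.0512) and Gm13169 by 2.68 ± 0.42 (adjusted p = 0.0206, called of the 6 fits only without placebo 3). Zfp981 was 58.5 times higher (95% interval 10 to 2350) and Zfp985 21 times higher (5.42 to 179), both called of those fits only without placebo 3. These zinc finger genes are near-identical copies, so their reads are uncertain.

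The libraries labelled DHT carried Y-linked transcripts, with a lowest value of 9.53 CPM over 4 Y-linked genes against a highest of 0.0997 CPM in placebo, which argues against DHT given to animals without a Y chromosome as their source. Their mean Xist was 0.292% of the placebo mean, which is consistent with male animals in those libraries, a hypothesis found and tested on the same data. A mixture of female and male liver RNA would keep part of Xist, and the highest value in a library labelled DHT was 2.39% of the lowest in placebo. Because 0 of the libraries labelled DHT lacked Y-linked transcripts, DHT and sex as sources of the sex-biased liver gene changes cannot be told apart, and the same holds for every other difference between the groups. The labels name the DHT animals as a model of polycystic ovary syndrome, a condition of the ovary. Y-linked transcripts in these libraries are at odds with that label. Whether male animals were used on purpose, or animals or labels were mixed up, stays open.

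The preset lists of clock genes with opposite phases moved apart. The mean log2 fold change was 2.29 over 5 Bmal1 phase genes and −1.15 over 11 E-box phase genes, a difference of 3.44 ± 1.06 (SE; exact permutation test, two-sided p = 0.0025 over all 4368 relabellings of the genes, which are not independent replicates). A coordinated difference in clock phase or amplitude could give this, a hypothesis found and tested on the same data. Not all E-box phase genes went that way. Adjusted over that list alone 2 rose and 7 fell, and its member Nr1d1 had 1.70 ± 0.36. With an estimated correlation camera called neither list (adjusted p = 0.177 for the Bmal1 phase and 0.0936 for the E-box phase). After removal of gene length and GC trends 10 clock genes were called, Nr1d1 (1.69) among them, and 8 before. Calls over all genes rose as well, so these counts cannot decide on such bias. The log2 fold changes of the 8 were then 5.28 for Npas2, 3.05 for Arntl, 1.55 for Clock and −3.85 for Usp2. They were −2.78 for Ciart, −3.02 for Per1, −2.29 for Per3 and −1.70 for Dbp. The trends that were removed thus did not account for these changes. Livers collected at different times of day could give such a pattern, and with 0 labels that give a time of collection this cannot be told apart from an effect of the treatment or of sex.

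Placebo 3 and DHT 3 deviated together from the other libraries of their groups (r = 0.602 across genes, with PC2 scores of −65.0 and −47.6 on a component of 33.7% of the variance). After removal of gene length and GC trends their deviations still correlated at 0.519, which argues against that bias as the whole cause, although it may account for part. Before removal, deviations from the gene means correlated with exon length (Spearman) at −0.00944, 0.249 and −0.394 in placebo 1, 2 and 3. The values were 0.299, 0.251 and −0.0375 in DHT 1, 2 and 3. With GC content they were negative only in placebo 3 (−0.278) and DHT 3 (−0.164). The median exon length was 2412.5 bases in genes called lower, 3449 in those called higher and 3721 in the rest. A separate day or batch for each number would part libraries 1 and 2 as well, and their differences correlated between the groups at −0.161. A day or batch shared by placebo 3 and DHT 3 alone would not part libraries 1 and 2, so this value cannot decide on it. What placebo 3 and DHT 3 share stays open.

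Of the 10 splits of the 6 libraries into 3 against 3, 1 gave as many genes as the labelled groups, the labelled one itself (250 genes, against 0 in the highest of the others), and 2 gave as many lists (14, against 15 in the highest of the others). The splits are too few for a share under 0.05. The split with 15 lists set placebo 1, DHT 1 and DHT 3 against the rest. Camera p was as small as in the labelled groups in 3 splits of the 10 for cholesterol synthesis (4.08e-07, smallest in the others 9.83e-28), steroid metabolism (0.0297 and 0.00997) and xenobiotic metabolism (3.24e-05 and 4.77e-06). It was so in 2 for interferon response (0.000157 and 2.13e-05) and in 6 for fibrosis (0.0127 and 9.04e-11) and oxidative phosphorylation (0.00373 and 3.98e-06), the labelled split included. Between 82 and 1503 genes passed an unadjusted p under 0.05 in the 9 other splits, against 2409 in the labelled one. With the replicate block the 3 other splits that part all 3 pairs called 0 genes each, against 1621. Each other split mixes the labelled groups, so the difference between those groups adds to the spread within each side. The 0 counts of genes therefore do not measure false calls, with or without the block.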
